A study of Drosophila melanogaster with 3 samples.

How the data were processed

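Elba2 binding was measured by chromatin immunoprecipitation and sequencing in 3 biological replicates, per the labels, of embryos aged 0 to 4 h from transgenic flies carrying Elba2 fused to enhanced green fluorescent protein, with an antibody to the tag. Chromatin was sheared by sonication to 200 to 800 bp, per the labels' protocols. The pull-down recovers DNA crosslinked to the fusion protein directly or through partners, and the fragment length limits how closely a summit marks the contact.

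The deposited files are peak lists in narrowPeak form. Per the file headers and the notes deposited with them, a permissive list of peaks and background was called for each replicate and for the 3 replicates pooled, each against a control library, and an optimal set was taken from these by irreproducible discovery rate (IDR). The lists are on builds dm6 and dm3. The aligner, the peak caller and the IDR threshold are not given in the sources used here, and the control library was not used here. The authors' signal value in each list is of unstated scale and was used only to rank or filter peaks within that list. The deposited −log10 q-value column served only to break ties. The deposited summit offset, a position and no measurement, gave the summit. In the pooled dm6 list, the 3276 optimal peaks were exactly the 3276 regions with the highest signal, with a lowest value of 109 out of 28496 regions. Replicates 2 and 3 each hold exactly 30000 regions. Because read numbers were not used, depth is unknown, differences in depth between replicates cannot be corrected, and its effect on weak peaks was not measured. Exact (Clopper-Pearson) 95% intervals cover counting error over peaks or genes only.

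Sequence came from the Release 6 genome, the assembly of dm6, and genes from Ensembl release 115 with FlyBase annotation 6.54. Region ends lay within the reference arms. The dm3 lists were used for counts alone, since no dm3 reference was used here. Coordinates are 1-based on dm6. Arms 2L, 2R, 3L, 3R, 4, X and Y were used. Background regions were the 23209 regions of the pooled list over 1000 bp from each optimal summit. They are weak pull-down regions, not random sequence, so contrasts with them are relative to weak signal.

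Summits within 200 bp counted as the same site, and replicates were compared at their top 3276 regions by signal, tested by 100000 circular shifts along the arms (10000 for alternatives). A promoter summit lay within 500 bp of any annotated TSS. The other classes were assigned in the order 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic, and 1000 circular shifts gave the genome-wide level. Words were searched on both strands within 100 bp of the summit and, as a second level, 400 to 600 bp away. Shares were compared by two-sided Fisher's exact tests, which treat peaks, genes and intervals as independent. Benjamini-Hochberg adjustment covered the 13 words other than the ELBA site and the palindrome, and the 28 gene lists. Smaller p-values than 1e-300 were set to that value. A peak within 500 bp of the TSSs of several genes was counted for each, so neighbouring genes of one list can share a peak. List members were matched by symbol to protein-coding genes, 28 symbols through synonyms, and 9 written symbols matched none. Among these 9 were Dl of the Notch pathway list and nos of the maternal patterning list. The chorion list, built from a symbol pattern, also took in Cp190 and Cp110, which are centrosomal protein genes.

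Groups, tests, gene lists, words and most alternatives were fixed before the data were examined. Genes were named by a rule of the same kind. It took the nearest gene of the 20 strongest promoter peaks. In each list it took up to 4 bound members with the highest signal and up to 3 unbound members in alphabetical order. It always took the ELBA, Hox and insulator protein genes. Genes sharing a promoter with the 20 strongest peaks, the gene Ama the gene pairs of divergent intervals and the peaks away from promoters were named after their values were seen. Alternatives changed the set to its strongest 1638 peaks, to the 1844 peaks among the top 3276 of all replicates, or to regions shared by 2 replicates without the other one. The Hox spans were extended by 500 bp on each side after the first map left out a peak at an Abd-B TSS. The alternatives also changed the distances (50, 100, 200, 250, 500 and 1000 bp where they apply), the interval lengths, the TSS set, and the background (matched on GC content in 2% bins, up to 3 regions per peak, or at promoters only). Further alternatives added after the data were seen were the use of background regions for intervals, of genes with any pooled region as reference for lists, and of genes with either word for the X.

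The functions were tested on simulated data with 3000 summits in the real genome. A planted ELBA site share of 10.5% came back as 10.7%, a promoter share of 48.2% as 49.1%, a shared summit percentage of 69.5% as 69.8%, and a list planted at 50% as 50%. The planted word ranked 1. An unplanted control word had an odds ratio of 0.883. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.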

Results

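Binding of Elba2 along the Drosophila melanogaster genome was measured by chromatin immunoprecipitation and sequencing in embryos of both sexes aged 0 to 4 h. Elba2 is a subunit of ELBA, a complex that binds insulator DNA in the early embryo, and one of its DNA-contacting BEN-domain proteins. The flies carried Elba2 fused to green fluorescent protein, and an antibody to that tag pulled down the chromatin. The 3 samples are biological replicates of 1 group, and no untreated or input sample is among them. The control library against which the authors called peaks was not used here. Lists of 29295, 30000 and 30000 regions came from replicates 1, 2 and 3, a list of 28496 regions from the 3 replicates pooled, and 3276 optimal peaks from the authors' test of irreproducible discovery rate (IDR), all on build dm6. Read counts were not used here, so the depth behind each peak is unknown. The signal value of each peak is the authors' own and has no replicate error, and ranks in the 3 replicate lists are given for part of the peaks named. A gene is called bound below where an optimal IDR summit lay within 500 bp of one of its annotated transcription start sites (TSSs).

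How far the replicates gave the same sites was asked first. The strongest peak of all, upstream of Dpm3, a subunit of dolichol-phosphate mannose synthase, ranked 1 in each replicate. The peaks at alc, the beta subunit of AMP-activated kinase, and at ACC, the acetyl-CoA carboxylase of fatty acid synthesis, ranked 3, 6 and 3 and 4, 4 and 2 in replicates 1, 2 and 3. The peak at Trl, the gene of GAGA factor, ranked 2258, 10668 and 1045, and the one at sob, an odd-skipped family gene, ranked 1865, 2900 and 17952. Taking the top 3276 regions of each replicate, 72.1% of summits in replicates 1 and 2 lay within 200 bp of each other, 66.0% in replicates 1 and 3, and 64.7% in replicates 2 and 3 (mean 67.6% ± 3.96, SD over 3 pairs). Circular shifts along the chromosome arms gave a mean of 0.955% and at most 7.06% (one-sided permutation p = 1e-05, the smallest that 100000 shifts can give). The shifts did not keep regions at promoters, so the test does not separate shared Elba2 sites from a shared preference for promoters. Of the optimal peaks, 81.0% ± 4.72 (SD, n = 3) were among the top 3276 regions of a replicate, and 1844 of them (56.3%) were so in all 3. The optimal set was taken from the replicate and pooled lists, so this recovery is no independent check. Across peaks, which are not independent, Spearman's rho between the signal values of 2 replicates was 0.649, 0.518 and 0.541.

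Binding lay mostly at promoters. Among the 20 strongest promoter peaks, 9 had a further protein-coding gene within 500 bp. Besides Dpm3, alc and ACC they included px, a wing vein patterning gene (signal rank 2), CG5087 with smg, the repressor of maternal mRNAs (rank 5), CG14100 (rank 6), and ben, a ubiquitin-conjugating enzyme (rank 7). CROT with CG12877 (rank 10), the zinc-finger gene crol (rank 12), Art3 with mRpS10 (rank 13) and the Polycomb gene ph-p (rank 14) followed. The remaining ones lay at CG14104 with the importin gene Kap-alpha1, the protein kinase C gene Pkc98E, POSH with Ns2, CG12384, FoxK with mRpL2, spg, CG8372 with CG8360, the chromosomal protein gene Chro with Ssl1, and the ESCRT-III gene CHMP2B with Tcs5. All 20 were found in every replicate, none ranked below 134 in any of them, and their signal values ran from 683 to 1355. The Dpm3 summit was at 3R:13403264, in the peak 3R:13403086 to 13403442, 213 bp from the TSS. The alc summit was at 2R:9137919, in the peak 2R:9137773 to 9138099, 14 bp from the TSS, and the ACC summit at 2R:7989218, in the peak 2R:7989010 to 7989400, 496 bp from a TSS. The ACC call was lost without replicate 2, without replicate 3 and within 250 bp of a TSS.

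Of the 3276 summits, 2002 (61.1%, exact 95% interval 59.4 to 62.8) lay within 500 bp of a TSS. Weak regions of the pooled list over 1000 bp from every optimal summit served as background, and 6158 of 23209 (26.5%) did so (odds ratio 4.35, two-sided Fisher's exact test, p at or below 1e-300). The 1000 bp limit keeps weak regions beside promoter peaks out of the background, which may lower its share of 26.5% and was not measured. Shifted positions gave 13.6%. In the 3 replicates the promoter share of the top 3276 regions was 63.6%, 60.3% and 57.7% (60.5% ± 2.97, SD, n = 3). Introns held 21.9% of summits against 35.2% of background regions, coding exons 3.75% against 12.9%, and sequence between genes 9.80% against 18.6%. The median distance to the nearest TSS was 234.5 bp, against 1579 bp in the background. Fisher's exact test treats peaks as independent, which neighbouring peaks are not.

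**Figure D1:**
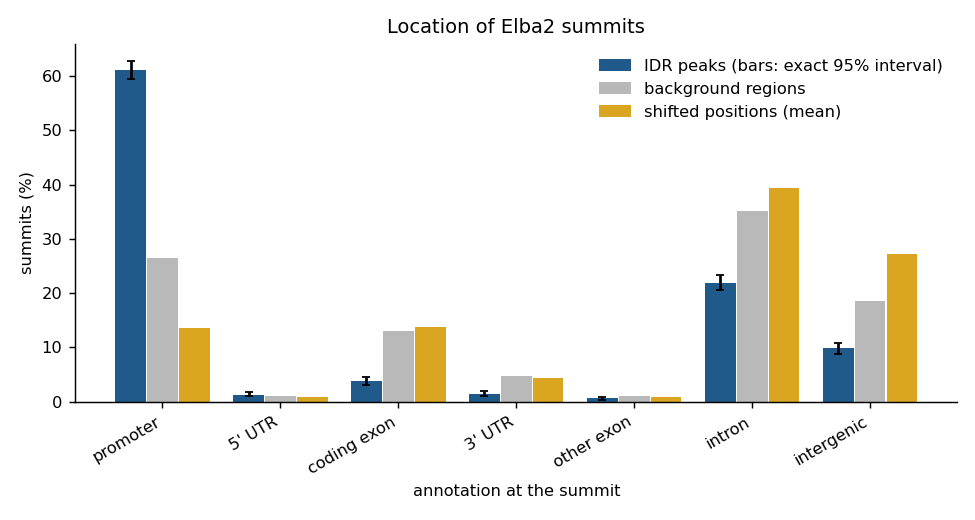
Share of summits (percent, vertical axis) in each annotation class (horizontal axis) for the 3276 optimal IDR peaks with exact 95% intervals, the 23209 background regions and circularly shifted positions. Promoters hold 61.1% of peaks, 26.5% of background regions and 13.6% of shifted positions, and the optimal peaks lie below both in introns, coding exons and sequence between genes.

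Whether Elba2 peaks carry the known binding sites was tested with fixed words. CCAATAAG, the asymmetric site of ELBA, lay within 100 bp of the summit at wg, the Wnt ligand of segment polarity (2L:7306904, signal 509, ranks 83, 170 and 41 in the replicates). It was also found at Pkc98E, Rpt4, a proteasome ATPase, Pglym78, a glycolytic mutase, scw, a BMP ligand, sls, the titin-like muscle gene, and Abd-B. CCAATTGG, the palindrome bound by the related BEN-domain protein Insensitive, lay at alc, CG5087, crol, spg, CG8372, the pair-rule gene opa, the segment polarity genes hh and mid, the bromodomain gene fs(1)h and RpL29. Neither word was present at the Dpm3, px, ACC, CG14100 and ben peaks, and 7 of the 20 strongest promoter peaks had either one.

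The ELBA site was found at 226 of 3276 summits (6.90%, exact 95% interval 6.05 to 7.82) and at 1.91% of background regions (odds ratio 3.80, Fisher's exact p = 2.89e-48). Flanks 400 to 600 bp away had it in 0.458%. The palindrome was found at 300 summits (9.16%, 8.19 to 10.2), at 1.78% of background regions (odds ratio 5.55, Fisher's exact p = 9.17e-91) and in 0.473% of flanks. In the top 3276 regions of single replicates the shares were 6.86% ± 0.354 for the ELBA site and 8.65% ± 0.717 for the palindrome (SD, n = 3). The ELBA site read backwards, a control word of the same bases, was found at 0.397% of summits and 0.336% of background regions (odds ratio 1.18, Benjamini-Hochberg adjusted p = 0.759, Fisher's exact test). Copies within 100 bp had a median distance to the summit of 29.5 bp for the ELBA site and 22.5 bp for the palindrome. Both words together occurred at 20 peaks, and 2770 peaks (84.6%) had neither. Peaks with neither word lay at promoters more often than peaks with either (63.6% against 47.4%). The promoter share of all optimal peaks thus rests mainly on peaks with neither word, for which unspecific pull-down stays open, as set out below.

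**Figure D2:**
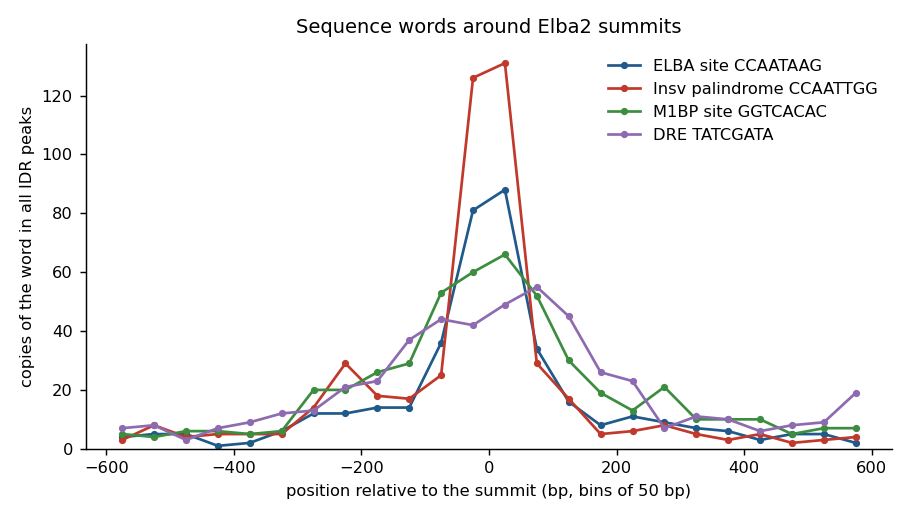
Copies of 4 words in all 3276 optimal IDR peaks (vertical axis) per 50 bp bin of position relative to the summit (horizontal axis, bp). Counts in the bin just right of the summit are 131 for the palindrome, 88 for the ELBA site, 66 for the M1BP site and 49 for the DRE. The M1BP site and the DRE are spread more broadly, and the DRE is highest (55) in the next bin.

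Peaks with a high signal carried the words more often. In 5 groups of equal size from the strongest to the weakest peaks, the ELBA site was present at 11.1%, 7.48%, 6.87%, 5.50% and 3.51%. The strongest 655 peaks exceeded the weakest 655 (73 against 23 peaks, odds ratio 3.45, Fisher's exact p = 1.12e-07). The palindrome was present at 16.2%, 9.31%, 8.85%, 5.19% and 6.26% of these groups, so the weakest peaks had it more often than the group before them, and the strongest exceeded the weakest 655 peaks (odds ratio 2.89, Fisher's exact p = 1.31e-08). Without replicate 1, in regions shared by the other replicates and ordered by the signal of replicate 2, the odds ratio of the ELBA site fell to 1.50 and the call was lost (Fisher's exact p = 0.136). It was 1.74 without replicate 2, 2.03 without replicate 3, 1.78 in the 1638 strongest peaks, 1.79 in the 1844 peaks found in all replicates and 2.24 with a window of 200 bp. The odds ratio of the palindrome fell to 1.87 without replicate 2 (Fisher's exact p = 0.00458).

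**Figure D3:**
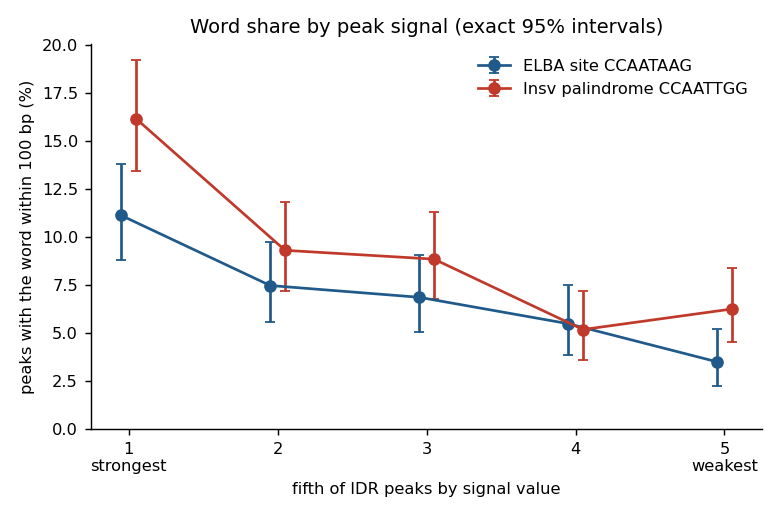
Share of optimal IDR peaks with each word within 100 bp of the summit (percent, vertical axis) in 5 groups of equal size by signal value (horizontal axis, strongest first), with exact 95% intervals. The ELBA site share goes from 11.1% to 3.51% and the palindrome share from 16.2% to 6.26%, with 5.19% in the group before the weakest.

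Sites of other early-embryo and insulator factors were compared in the same way, as 13 further words. The M1BP site GGTCACAC, a core promoter element of housekeeping genes, was at 6.72% of summits against 1.57% of background regions (odds ratio 4.52, Fisher's exact test, adjusted p = 3.23e-55). The DRE TATCGATA, bound by Dref and BEAF-32, was at 5.34% against 1.80% (odds ratio 3.08, Fisher's exact test, adjusted p = 1.49e-28). The GAGA repeat was at 5.16% against 3.38% (odds ratio 1.55, adjusted p = 3.55e-06) and the CTCF core at 2.08% against 0.974% (odds ratio 2.16, adjusted p = 1.12e-06), all by Fisher's exact test with Benjamini-Hochberg adjustment over the 13 words. The shares over the 3 replicates were 6.27% ± 1.09, 4.82% ± 0.782, 5.22% ± 1.20 and 1.96% ± 0.157 (SD, n = 3). The site of Zelda, the pioneer activator of the zygotic genome, was at 1.65% against 1.44% (adjusted p = 0.570, Fisher's exact test), and the other 8 words also did not pass. Under alternatives the CA repeat passed with the 1638 and the 1844 peaks, without replicate 2 and with a window of 200 bp (odds ratios 1.34, 1.34, 1.29 and 1.38), and the Caudal site without replicate 3 (1.19), which raised the count of words from 4 to 5. Against a background matched on GC content, the Bicoid and Caudal sites passed as lower (0.800 and 0.879). When only promoter summits were compared with promoter background regions, the count of words that passed fell from 4 to 2. The M1BP site kept an odds ratio of 2.23 (Fisher's exact p = 1.48e-16) and the DRE one of 1.66 (Fisher's exact p = 7.41e-07). The GAGA repeat then had an odds ratio of 0.812 (Fisher's exact p = 0.122) and the CTCF core one of 1.19 (Fisher's exact p = 0.476).

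A scan of all 32896 words of 8 bases, ranked by share at summits minus share in flanks, put CCAATTGG at rank 2, CCAATAAG at rank 6, GGTCACAC at rank 7 and TATCGATA at rank 13. Rank 1 was CAATTGGA (11.2% of peaks against 1.33% of flanks), which overlaps the palindrome, and rank 3 was CAATAAGA (8.55% against 0.733%), which overlaps the ELBA site. CCAATAGG, at rank 14, was at 4.15% of summits and 0.0763% of flanks. The ELBA site ranked 5 or 6 under each alternative tried.

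Which gene groups carried Elba2 at their promoters was tested for 28 fixed lists. In all, 2495 of 13968 protein-coding genes (17.9%) were bound. Of the Polycomb and Trithorax group genes, which keep developmental genes off or on, 17 of 32 were bound (odds ratio 5.24, Fisher's exact test, adjusted p = 6.24e-05), among them ph-p, fs(1)h, E(z), the histone methyltransferase, and brm, the chromatin remodelling ATPase. Their signal values were 786, 440, 287 and 252, and their ranks in replicates 1, 2 and 3 were 15, 3 and 76 for ph-p, 146, 83 and 199 for fs(1)h, 543, 411 and 2911 for E(z), and 686, 281 and 2004 for brm. Of RNA polymerase II subunits and general transcription factors, 16 of 32 were bound (odds ratio 4.62, Fisher's exact test, adjusted p = 0.000158), with TfIIB (291), Polr2H (236), Taf5 (215) and Polr2B (201) the strongest. Of cytosolic ribosomal protein genes, 36 of 93 were bound (odds ratio 2.93, Fisher's exact test, adjusted p = 2.62e-05), with RpL29 (493), the related gene RpLP0-like (408), RpL9 (319) and RpL41 (302) in front. Of mitochondrial ribosomal protein genes, 25 of 73 were bound (odds ratio 2.41, Fisher's exact test, adjusted p = 0.00262), led by mRpS10 (794), mRpL2 (697), mRpL41 (648) and mRpS23 (603), of which mRpS10, mRpL2 and mRpS23 share their peak with Art3, FoxK and CenG1A. Unbound members included Pc, Asx and Caf1-55, Polr2A, Polr2E and Polr2G, RpL10, and mRpL1.

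Binding was less frequent than among other genes in 3 lists. None of 97 cuticle protein genes (adjusted p = 2.70e-07), 60 odorant receptor genes and 60 gustatory receptor genes (adjusted p = 6.29e-05 each, Fisher's exact test) was bound, which leaves out for example Ccp84Aa, Or10a and Gr10a. All p-values for lists are from two-sided Fisher's exact tests against the other protein-coding genes, adjusted over the 28 lists. In the 3 replicates the bound share was 45.8% ± 1.80 for Polycomb and Trithorax genes, 43.8% ± 5.41 for polymerase II and general factors, 35.8% ± 2.71 for cytosolic and 30.1% ± 5.97 for mitochondrial ribosomal protein genes (SD, n = 3). When the 7432 protein-coding genes with any region of the pooled list at a TSS served as the reference, an alternative added after the data were seen, 0 lists were higher and only the cuticle list was lower (Fisher's exact test, adjusted p = 0.0231). The odds ratios under this reference were 2.41 for the Polycomb and Trithorax list, 2.27 for the polymerase II list, and 1.49 and 1.42 for the cytosolic and mitochondrial ribosomal lists. Odorant and gustatory receptors stayed at an odds ratio of 0, with 0 of 11 and 0 of 6 genes bound (Fisher's exact test, adjusted p = 0.190 and 0.663), so their calls ended with fewer genes and not with a changed share. The odds ratio of the Polycomb and Trithorax list fell to between 2.98 and 3.29 without 1 replicate (9 to 11 of 32 genes). Its call was lost with the 1638 strongest peaks (odds ratio 2.08, 6 of 32 genes, Fisher's exact test, adjusted p = 0.361). It was also lost with the 1844 peaks found in all replicates (odds ratio 2.79, 8 of 32 genes, Fisher's exact test, adjusted p = 0.0682). The polymerase II list had an odds ratio of 2.78 without replicate 2 and lost its call with the 1844 peaks (Fisher's exact test, adjusted p = 0.0682). Mitochondrial ribosomal protein genes lost theirs with the 1638 and the 1844 peaks and without replicate 1 or 2 (odds ratios 2.14, 1.81, 1.81 and 1.69, Fisher's exact test, adjusted p = 0.0779, 0.199, 0.198 and 0.294).

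**Figure D4:**
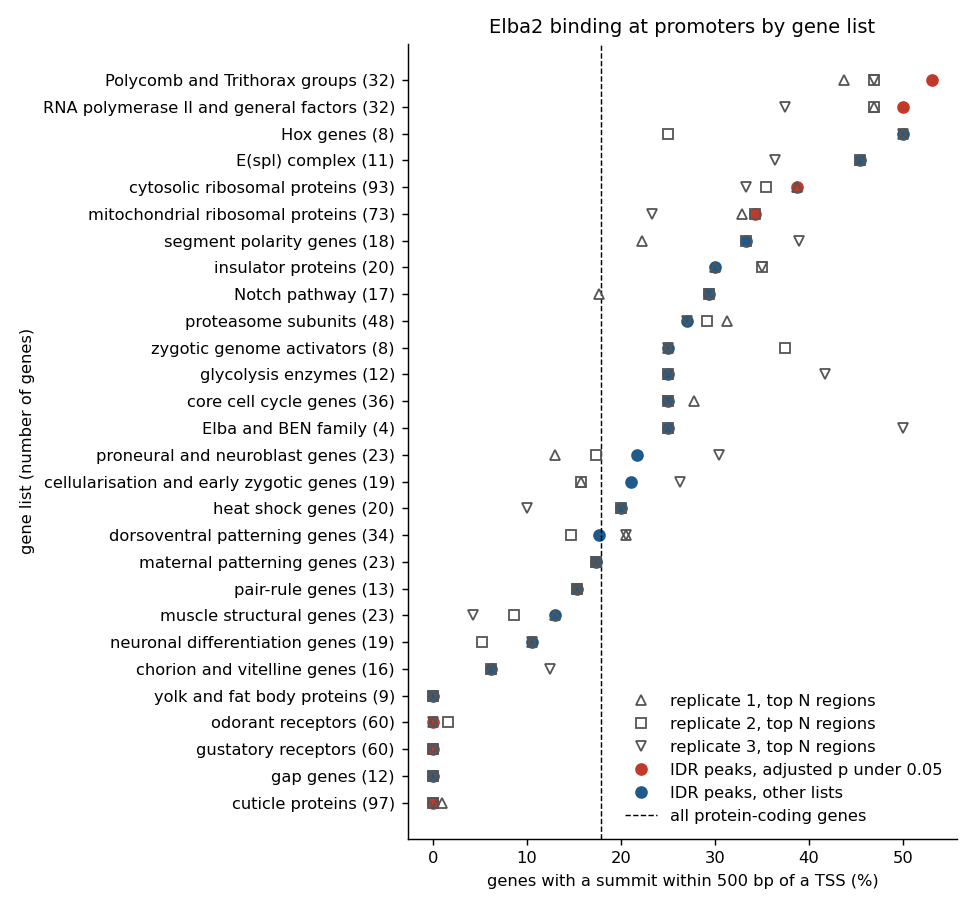
Share of genes in each list with a summit within 500 bp of a TSS (percent, horizontal axis), one line per list with its number of genes (vertical axis). Filled circles are optimal IDR peaks, open symbols the top 3276 regions of each replicate, and the dashed line marks all protein-coding genes (17.9%). The 4 lists that were higher lie between 34.2% and 53.1%, and the 3 that were lower at 0%.

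No other list passed the adjusted test on the full set of optimal peaks. Among segment polarity genes 6 of 18 were bound (adjusted p = 0.322, Fisher's exact test), with wg (509), mid (270), hh (260) and H15 (189) ahead and arm, ci and en unbound. Of the gap genes, 0 of 12 were bound (adjusted p = 0.326, Fisher's exact test), Kr, btd and cnc included. Of pair-rule genes 2 of 13 were bound, opa (364) and sob (117), and eve was unbound. Of dorsoventral genes 6 of 34 were bound, with tin (183), the Toll pathway inhibitor cact (167), scw (153) and tsg (129) the strongest, and Doc1 and Ance were unbound. Of cellularisation and early zygotic genes 4 of 19 were bound, which were Bro (335), nullo (155), tsg and E(spl)m5-HLH (114), and Sxl was unbound. Maternal patterning genes had 4 of 23 bound (bcd, swa, pll and pum), zygotic genome activators 2 of 8 (bcd and Trl, the other members including cad), and proneural and neuroblast genes 5 of 23, with numb (287), elav (266), brat (221) and nub (150) in front.

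Of Notch pathway genes 5 of 17 were bound, with the corepressor gro (330), H (162), fng (154) and Su(H) (142) the strongest, and of the E(spl) complex 5 of 11 (adjusted p = 0.113, Fisher's exact test), led by E(spl)mdelta-HLH (194), E(spl)m7-HLH (162), E(spl)m3-HLH (154) and E(spl)m2-BFM (124). Core cell cycle genes had 9 of 36 bound, with CycE (448), aurA (264), CycD (231) and Bub3 (153) ahead and Cdk2 unbound. The aurA and E(spl)m7-HLH peaks had no region of replicate 3 within 200 bp. Proteasome subunits had 13 of 48 (adjusted p = 0.325, Fisher's exact test), with Rpn7, Rpt3, Rpt4 and Prosbeta1 the strongest. They passed with the 1844 peaks found in all replicates, without replicate 1 and without replicate 2 (Fisher's exact test, adjusted p = 0.0216, 0.0406 and 0.0291). Heat shock genes had 4 of 20 bound (Hsc70-4, Hsp83, Hsp27 and Hsc70-5), glycolysis enzymes 3 of 12 (Pglym78, Ldh and Gapdh2), muscle structural genes 3 of 23 (Tm1, sls and Msp300), neuronal differentiation genes 2 of 19 (elav and nSyb), and yolk and fat body proteins 0 of 9. In the chorion and vitelline list 1 of 16 was bound, and that member, Cp190, encodes a centrosomal and insulator protein and no eggshell component. Among the genes named for these lists, the calls at pum and Msp300 were lost whichever replicate was left out. Those at bcd, sob, Bub3, Hsp27, Hsc70-5, sls, E(spl)m2-BFM, E(spl)m3-HLH and E(spl)m7-HLH were lost without replicate 1 or 2, those at tsg, Su(H) and nSyb without replicate 1 or 3, and those at nub, H, fng and E(spl)m5-HLH without replicate 2 or 3. With the 1844 peaks found in all replicates all of these calls were lost, and with the 1638 strongest peaks all but those at bcd, H and E(spl)m7-HLH, and also those at nullo, scw, swa and pll.

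The genes of ELBA itself and of insulator proteins were always read out. Elba1, Elba2 and Elba3 were not bound, and insv, the gene of Insensitive, was (2L:2576804, signal 149, ranks 4213, 1884 and 631). On the minus strand, insv reaches to 2L:2576997, and Elba2 starts at 2L:2577687 on the plus strand. The insv peak thus also lies near Elba2, but over 500 bp from its TSS. The call at insv was lost without replicate 2, without replicate 3, and with the 1638 and the 1844 peaks, and all 4 genes of this list had some region of the pooled list at a TSS. Among the top 3276 regions of replicate 3, 50% of the 4 genes were bound, against 25% in replicates 1 and 2. The insv peak ranked 4213 in replicate 1, outside its top 3276. The 25% in replicate 1 thus comes from another summit, and its gene was not read out. Of 20 insulator protein genes 6 were bound (adjusted p = 0.326, Fisher's exact test), which were Chro (685), Cp190 (376), M1BP (166), Dref (124), Trl (118) and BEAF-32 (113). Those at Dref, Trl and BEAF-32 were lost with the 1638 and the 1844 peaks and without replicate 1 or 3, and BEAF-32 also without replicate 2. CTCF, su(Hw), mod(mdg4), pita, ZIPIC, dwg, pzg, Clamp, Ibf1, Ibf2 and the cohesin genes SMC1, SMC3, vtd and Nipped-B were unbound.

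The Hox genes set segment identity, and those of the bithorax complex are separated by insulators. Of 8 Hox genes 4 were bound (adjusted p = 0.120, Fisher's exact test), which were abd-A (366), Scr (237), Abd-B (145) and lab (131), while Antp, Dfd, Ubx and pb were not. Abd-B and lab lost their calls with the 1638 and the 1844 peaks and without replicate 1 or 3. Without replicate 2 the list passed (adjusted p = 0.0433, Fisher's exact test). From 500 bp before to 500 bp after its Hox genes, the bithorax complex (3R:16656123 to 16972736) held 12 peaks (37.9 per Mb) and the Antennapedia complex (3R:6660927 to 6999728) held 10 (29.5 per Mb), against 25.0 per Mb on the whole arm 3R. No test was run on these densities. The strongest peak of the bithorax complex, 3R:16919221 to 16919344, lay in an intron of the noncoding gene lncRNA:iab8 between abd-A and Abd-B (signal 460, ranks 101, 163 and 130). An ELBA site lay under the intronic peaks 3R:16898749 to 16899172 in lncRNA:iab8 and 3R:16932115 to 16932538 in Abd-B, and a palindrome under the Abd-B intron peak 3R:16962319 to 16962742. The peak at an Abd-B TSS, 3R:16972133 to 16972556, also had an ELBA site. In the Antennapedia complex no peak had either word, and its peaks with the highest signal values lay in an Antp intron (245), near the Scr TSS (237) and at Ama (210).

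**Figure D5:**
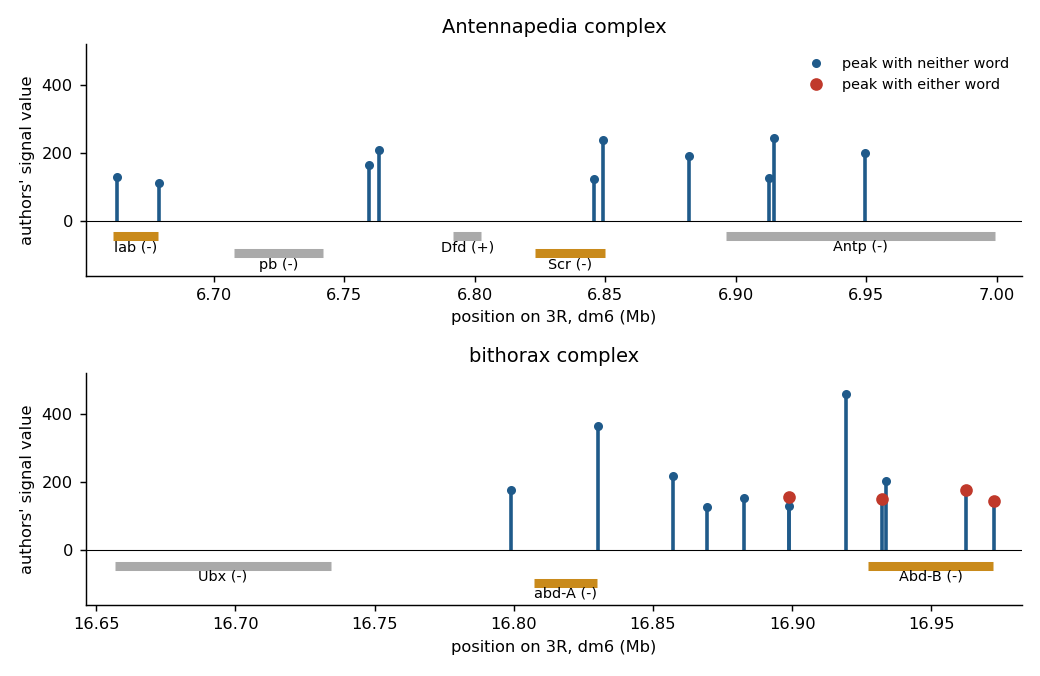
Optimal IDR peaks (lines and points, authors' signal value on the vertical axis) along both Hox complexes (horizontal axis, position on 3R in Mb, build dm6), red where either word lies within 100 bp of the summit. Bars below are the Hox genes with their strand, orange where bound and grey where not. The bithorax complex holds 12 peaks and the Antennapedia complex 10.

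Intervals of 200 to 2000 bp between neighbouring protein-coding genes were compared by orientation. A divergent interval is flanked by 2 gene starts, a tandem one by 1 and a convergent one by 0, so the order below was not separated from the promoter share of 61.1%. The strongest peaks between divergent gene starts lay between CROT and CG12877, Art3 and mRpS10, Ns2 and POSH, and Tcs5 and CHMP2B (signal 813, 794, 724 and 683). Of 1834 divergent intervals 431 held a summit (23.5%, exact 95% interval 21.6 to 25.5), of 2740 tandem ones 204 (7.45%, 6.49 to 8.49), and of 546 convergent ones 17 (3.11%, 1.82 to 4.94). Divergent intervals exceeded convergent ones (odds ratio 9.56, Fisher's exact p = 3.39e-34) and tandem ones (odds ratio 3.82). Background regions showed the same order at 29.4%, 21.8% and 14.8%, with a divergent to convergent odds ratio of 2.40, an alternative added after the data were seen. These regions lie over 1000 bp from each optimal summit, which keeps them out of many intervals that hold a peak, so 2.40 is not a level for 9.56. In intervals of 2000 to 10000 bp the odds ratio was 1.82 (Fisher's exact p = 0.0235). Of the 2002 promoter peaks, 822 (41.1%) had at least 2 protein-coding genes within 500 bp.

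Genes on the X were bound less often than autosomal genes, although ben and ph-p on the X were among the strongest. On the X, 331 of 2196 protein-coding genes were bound (15.1%, exact 95% interval 13.6 to 16.6), against 2153 of 11669 on 2L, 2R, 3L and 3R (18.5%, 17.8 to 19.2; odds ratio 0.784, Fisher's exact p = 0.000131). The odds ratio was 0.771, 0.704 and 0.818 in replicates 1, 2 and 3, so it was lower on the X in 3 of 3. Shares of the 4 autosomal arms in the test ran from 16.8% on 2L to 19.8% on 3R, and chromosome 4, which the test left out, had 11 of 80 genes bound (13.8%), below the X. Among genes with either word within 500 bp of a TSS, an alternative added after the data were seen, the direction turned, with an odds ratio of 1.23 that did not pass (Fisher's exact p = 0.223).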

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

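The optimal peaks on the older build dm3, which no comparison uses, include 13 outside the main chromosome arms. They stood out only because peaks were called in data left aside, above the 3 counts that a count of 0 allows, which is no test of whether more lie there than elsewhere. Of these, 5 lay on 2RHet, 4 on 3LHet, 2 on 3RHet, 1 on XHet and 1 on U, which hold heterochromatin and unplaced sequence. All 3276 optimal peaks on dm6 lay on the main arms, and none of them on the Y. No region of the dm6 pooled or replicate lists lay elsewhere either. Counts outside the arms can therefore not be set against each other between the builds. No explanation was tested, since positions were not carried from one build to the other. With 3 replicates in 1 group, single samples were not tested for standing apart and no groups were compared.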

How the results depend on the processing

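The reference of genes with any pooled region, the use of background regions for intervals and the restriction to genes with either word were chosen after the data were seen. Of 94 recomputed values for the main results, 87 kept their direction and their side of the threshold, or stayed within 1.5 times for counts and 1 SD for recovery. The 87 include the interval contrast in background regions (odds ratio 2.40). That value holds no optimal peaks, so it is no support for the result on peaks. The promoter odds ratio ranged from 3.84 to 4.73, that of the ELBA site from 3.17 to 4.86, that of the palindrome from 4.49 to 6.85, and replicate overlap from 60.5% to 72.1%. With promoter summits only, 2 further words were higher in place of 4, and the GAGA repeat turned to an odds ratio of 0.812. The number of lists that were higher was 4, and fell to 2 with the strongest 1638 peaks and to 2 with the 1844 peaks found in all replicates. Cytosolic ribosomal protein genes passed under both, polymerase II genes only with the 1638 peaks, proteasome genes only with the 1844, and Polycomb and mitochondrial ribosomal genes under neither. With genes that have any pooled region as the reference, 0 lists were higher and 1 was lower in place of 3, while odorant and gustatory receptors stayed at an odds ratio of 0 with 11 and 6 genes left. Without one replicate, the odds ratio of the ELBA site in strong against weak peaks was 1.50 to 2.03. For the X, genes with either word gave an odds ratio of 1.23. The fewer peaks in the stricter sets lower the power of the list tests, but the odds ratio of the Polycomb list also fell. It was 5.24 with all optimal peaks, 2.08 with the 1638 peaks and 2.79 with the 1844. Otherwise the cause was not tested. Of 93 named bound genes, 68 were bound by the strongest 1638 peaks, 69 by peaks found in all replicates, 74 to 77 without one replicate, 70 within 250 bp and 93 within 1000 bp. Depth is unknown, and what it limits was not measured.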

Other observations

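The tests on copies of the words in the genome were chosen after the data were seen, as were the peaks named here. The 5 strongest peaks away from promoters lay in an intron of Evi5 (X:11453341, signal 834, ranks 9, 22 and 7 in the replicates), in an intron of numb, a cell fate determinant of asymmetric division (2L:9453202, signal 822, ranks 14, 11 and 9), and between genes near Rh5, a rhodopsin gene (2L:12010666, signal 803, ranks 17, 13 and 10). The next were in an intron of Ufd4, a ubiquitin ligase (2L:10291481, signal 782, ranks 21, 17 and 8), and between genes near lncRNA:CR45102 (X:3704384, signal 764, ranks 34, 27 and 5). The Ufd4 summit had both words within 100 bp and the numb summit a palindrome, and the other 3 had neither.

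Few copies of the words in the genome were bound. An optimal summit lay within 100 bp of 239 of 4159 copies of the ELBA site (5.75%) and of 311 of 2964 copies of the palindrome (10.5%). Copies within 500 bp of a TSS were bound more often than others, 19.3% against 3.75% for the ELBA site (odds ratio 6.11, Fisher's exact p = 1.68e-33) and 27.9% against 6.48% for the palindrome (odds ratio 5.58, Fisher's exact p = 2.48e-40). The ELBA site read backwards had 14 of 2444 copies near a summit (0.573%), with 2.10% at promoters and 0.332% elsewhere (odds ratio 6.45, Fisher's exact p = 0.00119). The control word thus showed a similar promoter ratio at a far lower level.

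Of the tests below, some were chosen after the results were seen. These were the tests on genes without either word, on copies in the genome and on reproducibility without grouping by signal. The bound over all genes used for copy number was chosen then too. They replaced earlier choices, whose results are given beside them. No explanation that needs a comparison of groups was tested for these patterns, since the samples form 1 group.

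The 2770 peaks with neither word were the most frequent kind. Words 1 base away from either word were at 44.4% of their summits against 21.3% of their flanks, an excess of 23.1 percentage points (95% bootstrap interval 20.9 to 25.2) that is too small to account for most of them, although it may account for some. Low reproducibility stays open for part of them, since 53.2% were found in all 3 replicates against 73.1% of peaks with a word, a difference of −19.9 percentage points (−24.0 to −15.5), but 1474 of them were found in all 3. The earlier choice, within groups of similar signal, gave −5.18 (−8.06 to −2.37). That falls short of the limit used for the ungrouped difference, so the choices gave opposite answers. Peaks with neither word had a lower median signal (155, against 185 with the ELBA site only and 187 with the palindrome only). Signal largely sets which peaks are found, so the ungrouped difference partly restates this, and neither choice decides alone. Unspecific pull-down at promoters stays open too, since 63.6% of these peaks and 47.4% of peaks with a word were at promoters, a difference of 16.2 percentage points (11.8 to 20.6). The M1BP site was at 7.33% of these peaks and 3.36% of peaks with a word (odds ratio 2.27, Fisher's exact test, adjusted p = 0.00264). Because these peaks lay at promoters more often, and the test was not limited to promoter peaks, location may account for part of this. The DRE was at 5.70% and 3.36% (Fisher's exact test, adjusted p = 0.0623). The GAGA repeat and the CTCF core did not pass either (odds ratios 0.711 and 1.91).

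Fewer promoter words do not account for the lower bound share on the X. Genes without either word were bound less often there (odds ratio 0.688, 95% interval 0.596 to 0.795), while the earlier choice, the difference in genes with either word (8.52% of X and 7.31% of autosomal genes), was 1.21 percentage points with an undecided interval of −0.0139 to 2.44. A lower copy number of the X in embryos of both sexes was taken to lower all X genes alike. Genes with either word had an odds ratio of 1.23 (0.893 to 1.68), 1.78 times that of genes without one (1.26 to 2.52). The lower bound of 0.893 lies barely above the upper bound over all genes (0.890), but this cannot decide on copy number. Genes were called bound at a signal cutoff, and peaks with a word had higher signal. The median was 185 with the ELBA site only, 187 with the palindrome only and 155 with neither. A loss of signal could thus cost more calls among genes without a word. The median signal was 154 for X peaks and 160 for autosomal peaks, which was not tested. By the bound of 1 set earlier the test was undecided, so copy number stays open.

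The palindrome was 1.33 times as frequent as the ELBA site at summits (95% bootstrap interval 1.12 to 1.56). Its frequency over the whole arms does not explain this, since copies there stood at a ratio of 0.713 (0.680 to 0.747). However, 61.1% of summits lie at promoters. Copies within 500 bp of a TSS numbered 556 for the palindrome and 535 for the ELBA site. At promoters, 155 of these palindrome copies (27.9%) and 103 of these ELBA site copies (19.3%) were bound, and 6.48% and 3.75% elsewhere. The palindrome was thus bound more often per copy in both places, which argues against word frequency at promoters as the explanation. The difference between these shares was not tested. In the earlier choice, the flanks of the peaks, the ratio was 1.03, from 31 and 30 windows, with an interval of 0.634 to 1.74 that is too wide to decide.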
